A study of Rattus norvegicus with 16 samples.

How the data were processed

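Gene expression was measured by RNA-seq in 16 tissue samples from 4 Sprague-Dawley rats, with 4 samples in each of 4 groups. Per the labels, RNA was extracted with Trizol and treated with DNase, and stranded poly-A libraries were made with the TruSeq kit and 12 cycles of PCR and read from both ends over 100 cycles. The submitters' processing notes name FastQC 0.11.3, TopHat2 2.0.13, Bowtie2 2.2.1 and DESeq2 and the rat genome build rn5. The roles of these tools, the program that counted reads, the annotation and the strand setting were not given in the sources used here. The deposited values were whole-number counts per gene symbol, with no normalisation, for 14476 genes in 16 libraries. Genome positions are not given because no annotation of build rn5 was used, and symbols are printed as the table gives them. Antisense and overlapping genes cannot be told apart without the strand setting, and values for near-identical family members (the globins, the myosin heavy chains, and Np4, Defa5 and RatNP-3b of the defensin family) are uncertain because their shared reads may have been split.

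Each sample was assigned to its group and rat from its own label. The 4 groups were compared with edgeR 4.0.16 (quasi-likelihood F-test, R 4.3.3) on the counts. Libraries were scaled with TMM factors, genes with low counts were removed with filterByExpr, and 12857 genes were tested in a single model of group means over all 16 libraries, so that every comparison shared the same estimate of the spread. The comparisons were membrane against empty-defect tissue, bone beside the spacer against bone beside the empty defect, the difference between those 2 differences (the interaction), and defect tissue against neighbouring bone within each limb. P-values were adjusted by Benjamini-Hochberg within each comparison and a gene was called at an adjusted p under 0.05. Each adjusted p for a gene in the text comes from this edgeR test unless another tool is named. Levels are CPM, the counts scaled by TMM library size, given as mean ± SD over 4 libraries, and the standard error of a log2 fold change was obtained as its size divided by the square root of the F statistic.

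A total of 29 gene lists of cell types and pathways were written down from textbook knowledge before the data were examined, as were the design, the rule for naming genes and all alternatives other than those said to have been added. The lists held 441 entries, counting a gene in each list that names it, of which 404 were in the table. Mmp8, Mmp9, Mmp12, Vegfa, Sost and Dkk1 each stood in a pair of lists. Lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, and again with an estimated correlation per list, adjusted over the 29 lists. Directional and mixed fry tests were run beside them, and directional fry values are given for some lists of the comparisons of spacer with empty defect. Counts of list members past the threshold over all genes are accompanied by counts adjusted over the list alone. The level of a list in a library was the mean log2 CPM of its members with a prior count of 2. Of the calls made at the preset correlation, only that of the B cell and plasma cell list between empty-defect tissue and bone held with an estimated correlation. Camera asks whether a list moves more than other genes, and fry asks whether its genes move on balance in a single direction.

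Genes were named by a fixed rule. For the comparisons of spacer with empty defect these were the 6 largest changes in each direction among called genes with a mean of at least 5 CPM and no overlap between the groups' libraries, up to 3 called members of each list that passed camera at the preset correlation or had at least 3 called members, and a panel of 10 genes (Col1a1, Sp7, Bglap, Sost, Acp5, Bmp2, Vegfa, Il1b, Il6 and Prg4) whatever their result. For the comparisons of tissue with bone, the 3 largest changes in each direction were taken. Other genes are said to have been chosen after their values were seen. Values of some genes that the rule names are not reported here.

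Total counts per library ranged from 40472228 to 76815879, and every gene in the table had at least 1 count. The ribosomal precursor Rn45s took 0.390 to 2.66% of the counts of a library. Replicates were compared before they were averaged: the lowest chi-square per degree of freedom between libraries of a group was 83.1 and their correlations of log2 CPM were 0.907 to 0.983, so no pair agreed within sampling noise and all libraries were kept. The counts come from PCR-amplified reads without molecular identifiers, so depth describes counting error only, and the spread between rats set the precision. On data simulated from the real means and spreads with 100 genes changed 2-fold and 100 changed 4-fold, edgeR recovered 31% and 84% of them for membrane against empty-defect tissue (12749 genes), 26% and 90% for the bone comparison (12771 genes), and 3% and 59% for the interaction (12741 genes). In the first of these, 4.96% of edgeR calls, 15.9% of DESeq2 calls and 5.83% of limma-voom calls were false. The changed genes were drawn only from those with a mean over the groups above 5 CPM, so recovery of lower genes was not measured. The simulated genes varied independently of each other, with no rat effect and no shared muscle or marrow content. These shares therefore describe the simulation and may not hold for the real calls.

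Samples with the same number came from the same rat, per the labels, so the numbers pair the samples. The deviations of same-rat libraries from their group means correlated with a mean of 0.156 (-0.0727 to 0.496) between membrane and empty-defect tissue and 0.182 (-0.0655 to 0.494) between the bone groups. The reported fit has no block, and the fit with a replicate block called 47 genes in the former comparison and 454 in the latter. The other alternatives were RLE size factors, no filter and a stricter filter on low counts (at least 1 CPM in 4 libraries), DESeq2 1.42.0, limma voom with sample quality weights, a fit of only the 8 libraries compared, and leaving out each library in turn. A skeletal muscle covariate and an erythroid covariate, each the level of that list in a library, were added after the muscle and marrow content of the libraries had been seen. All splits of the 8 libraries of a comparison into groups of 4 (35 splits), and 100 drawn splits for the interaction, were refitted to count calls.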

Results

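The Masquelet technique treats a bone defect by placing a cement spacer in it, around which a vascular sheath of tissue, the induced membrane, forms before bone graft is added. The study asked how gene expression in tissues of the defect and in neighbouring bone differs when an osteotomy holds a polymethyl methacrylate (PMMA) spacer and when it is left empty. Each of 4 Sprague-Dawley rats had plated osteotomies on both sides, with a spacer on 1 side and no filling on the other, and tissue was taken at 4 weeks. The 4 groups, with 1 library per rat in each, were the induced membrane (IM), the tissue of the empty osteotomy (PFNU, pre-fibrous non-union in the labels), bone beside the spacer (PMMA bone) and bone beside the empty defect (BNED). Libraries held 40472228 to 76815879 counts, and the 10 most abundant genes took 10.8 to 25.0% of them.

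Defect tissue and bone separated along the first principal component, which held 48.0% of the variance. Membrane and PFNU libraries lay between -101 and -35.8 on it and bone libraries between 15.6 and 97.2. The PMMA bone library of rat 1, at 90.3, lay among the BNED libraries (47.6 to 97.2), and the other 3 PMMA bone libraries lay at 15.6 to 41.8. Markers of other tissues differed widely between libraries. Skeletal muscle genes took 2.56, 4.55, 18.3 and 23.8% of the counts in the membranes of rats 1 to 4 and 7.19 to 17.6% in PFNU. Erythroid genes, which stand for blood and marrow, took 4.15 to 7.23% of the counts in BNED and 0.436 to 1.33% in the PMMA bone of rats 2 to 4. In the PMMA bone of rat 1 their share was 7.83%. In the membranes it was 0.0345 to 0.146% and in PFNU 0.0871 to 0.435%.

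**Figure D1:**
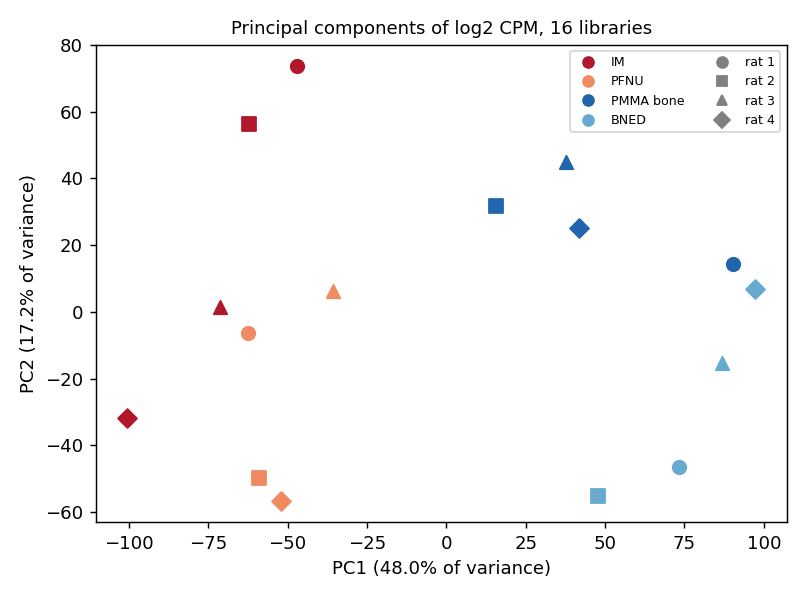
The first and second principal components of log2 CPM are plotted for 16 libraries, coloured by group with a symbol for each rat. Defect tissues (IM, PFNU) lie at -35.8 or below and bone at 15.6 or above on the first component, and the PMMA bone of rat 1 lies at 90.3 among the BNED libraries.

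**Figure D2:**
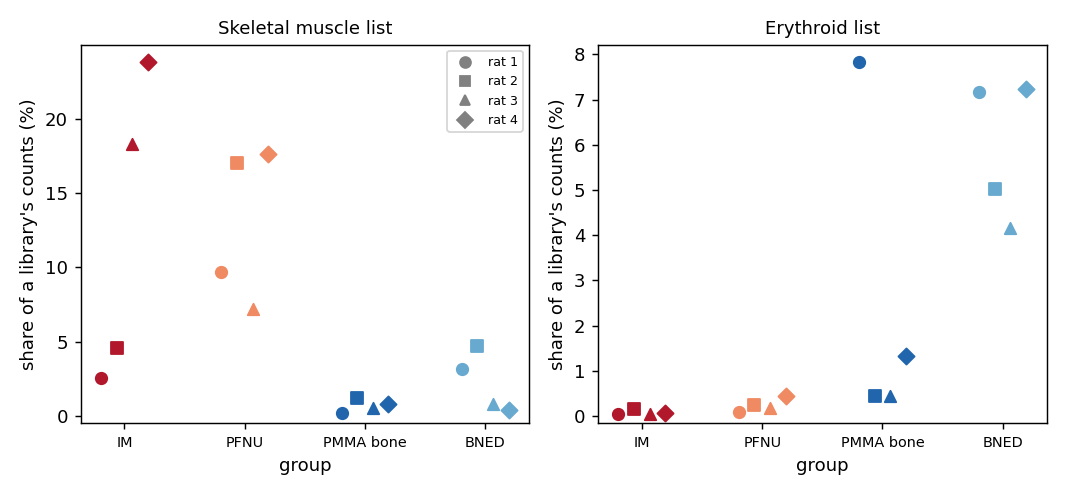
Each point is the share of a library's counts, in percent, taken by the skeletal muscle list (left) or the erythroid list (right), with 4 rats per group. Erythroid genes took 7.83% of counts in the PMMA bone of rat 1 and at most 1.33% in that of the other 3 rats.

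The membrane was compared with PFNU to see what the spacer changes in the tissue of the defect itself. B lymphocyte genes were lower in the membrane. Cd79b, a subunit of the B cell receptor, was at 2.49 ± 0.711 CPM (SD, n = 4) in the membrane and 16.4 ± 9.24 CPM in PFNU, a log2 fold change of -2.71 (SE 0.40, adjusted p = 0.00778). Rag1, which recombines antigen receptor genes in precursor lymphocytes, was at 0.199 ± 0.109 against 6.39 ± 5.24 CPM (adjusted p = 0.00778). Of 12 measured B cell and plasma cell genes, 7 fell and 5 did not pass the test, and 8 fell when adjusted over the list alone. The list had a median log2 fold change of -2.66 (camera adjusted p = 9.63e-18). It had adjusted p = 0.0889 with an estimated correlation and a directional fry adjusted p of 0.0128. The only other list that passed directional fry was the neutrophil list (adjusted p = 0.0348). Fry gave 0.0869 for the fibrous matrix list and 0.176 each for the erythroid, cartilage and macrophage lists. Of 16 neutrophil lineage genes, 7 fell (11 adjusted over the list alone), with a median of -2.46 (camera adjusted p = 3.41e-12, and adjusted p = 0.157 with an estimated correlation). Among them were S100a9, a calcium-binding protein of myeloid cells (4.52 ± 3.40 against 34.9 ± 19.8 CPM, log2 fold change -2.95, SE 0.58, adjusted p = 0.0300), the granule protein gene Ngp (log2 fold change -3.75, SE 0.74, adjusted p = 0.0300) and the neutrophil collagenase Mmp8 (log2 fold change -3.13, SE 0.59, adjusted p = 0.0266). Erythroid markers moved beside these groups, with a median of -2.22 over 11 genes (camera adjusted p = 1.21e-07, and adjusted p = 0.485 with an estimated correlation). None of the 11 was called by edgeR over all genes and 6 fell when adjusted over the list alone. An unadjusted p under 0.05 was found for 7, DESeq2 called 4 and limma-voom 0.

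Several muscle genes were among those lower in the membrane. Myh7, the slow myosin heavy chain, was at 6.75 ± 2.56 CPM (SD, n = 4) in the membrane and 1243 ± 1195 CPM in PFNU, where rat 4 alone reached 3031 CPM. Its log2 fold change was -7.52 (SE 1.10, adjusted p = 0.00778). The slow or cardiac isoforms Myl2 (log2 fold change -6.07, SE 1.00, adjusted p = 0.0176), Tnnt1 (-5.86, SE 1.03, adjusted p = 0.0220), Tnnc1 (-4.52, SE 0.95, adjusted p = 0.0390) and Myl3 (-4.44, SE 0.96, adjusted p = 0.0446) fell with it. Myh2 of fast oxidative fibres fell by 4.07 (SE 0.90, adjusted p = 0.0482). The fast-fibre genes Myh4 and Myh1, chosen after their values were seen, had log2 fold changes of 0.54 (SE 0.82, adjusted p = 0.827) and -1.72 (SE 0.86, adjusted p = 0.356). Of 17 skeletal muscle genes 3 fell, also when adjusted over the list alone. Of the 17, 11 had positive values. The list's median was 0.17, its mean -0.95 and its camera test downward (adjusted p = 0.00529, and adjusted p = 0.753 with an estimated correlation). Without the membrane of rat 1 the test did not pass (adjusted p = 0.313), and 1 gene fell without that library or PFNU of rat 4.

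A few genes of the extracellular matrix were higher in the membrane. Fbn1, which encodes fibrillin of elastic microfibrils, was at 1222 ± 199 CPM (SD, n = 4) in the membrane and 511 ± 164 CPM in PFNU (log2 fold change 1.26, SE 0.23, adjusted p = 0.0254). Loxl1, an enzyme that crosslinks elastin, rose by 1.35 (SE 0.28, adjusted p = 0.0349). Of 18 fibrous matrix genes, these 2 rose over all genes and 11 rose when adjusted over the list alone. All 18 had positive values (median 1.01, camera adjusted p = 3.41e-12, and adjusted p = 0.364 with an estimated correlation). Among called genes of at least 5 CPM with no overlap between the groups, the largest increases were of Gap43, a growth cone protein (log2 fold change 2.45, SE 0.51, adjusted p = 0.0351), Sbsn (2.03, adjusted p = 0.0300) and Gfpt2 of the hexosamine pathway (1.88, adjusted p = 0.0299). They were followed by Reln, a secreted matrix protein (1.86, adjusted p = 0.0294), Tgfbi, a collagen-binding protein (1.85, adjusted p = 0.0385), and Chpf, which extends chondroitin chains (1.76, adjusted p = 0.0323). Gap43 in the membrane of rat 2, at 52.9 CPM, and Sbsn, at 34.0 CPM, stood far above the other membranes. Of 18 matrix proteases and inhibitors Mmp8 alone was called. In that list 9 rose and 1 fell when adjusted over the list alone (median 0.86, camera adjusted p = 0.00161, and adjusted p = 0.654 with an estimated correlation). Cartilage genes had a median of 2.57 over 15 genes (camera adjusted p = 4.00e-06, and adjusted p = 0.485 with an estimated correlation) and macrophage genes 0.80 over 16 (7.02e-06, and adjusted p = 0.485 with an estimated correlation). No gene of either list was called by edgeR or limma-voom. In the former and the latter 10 and 8 had an unadjusted p under 0.05, DESeq2 called 2 and 4, and 0 and 6 passed when adjusted over the list alone. Adipocyte genes (median -0.45, adjusted p = 0.0353, and 0.753 with an estimated correlation) and immediate early genes (median 0.44, adjusted p = 0.0353, and 0.654 with an estimated correlation) also passed camera at the preset correlation. Adipocyte genes no longer did with a replicate block for rat (adjusted p = 0.0687) or without membranes 1 or 3 or PFNU of rat 2 (0.415, 0.227 and 0.596). Immediate early genes did not without membranes 1 or 3 or PFNU of rats 2 or 3 (adjusted p = 0.313, 0.119, 0.0636 and 0.0854), nor proteases without membrane 1 (adjusted p = 0.107). Fibrous matrix genes called numbered 1 without membrane 1 or 2, 4 without membrane 4 and 0 by edgeR without PFNU of rats 2, 3 or 4. Their median was 0.67 with a muscle covariate (2 called) and 0.35 with an erythroid covariate (0 called by edgeR). The camera adjusted p of 8.10e-06 and 0.00352 were at the preset correlation, and that with an estimated correlation was 0.364 without a covariate. With the muscle and the erythroid covariate protease genes had adjusted p = 0.188 and 0.859, immediate early genes 0.203 and 0.199, and adipocyte genes 0.115 and 0.646, and macrophage genes had 0.184 with the muscle covariate. Chosen after their values were seen, the BMP antagonists Nog (-2.33, adjusted p = 0.0447) and Nbl1 (1.32, adjusted p = 0.0482) and the Wnt agonist Rspo3 (-2.49, adjusted p = 0.0351) were called.

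None of the bone and growth factor genes of the fixed panel was called. Log2 fold changes were 0.95 for collagen gene Col1a1 (adjusted p = 0.447), -0.95 for Bmp2 (adjusted p = 0.242) and -0.86 for Vegfa (adjusted p = 0.375). Sp7, Bglap, Sost, Acp5, Il1b, Il6 and Prg4 had adjusted p of 0.605 to 0.997. Values of Sp7, Sost and Acp5 in the membrane of rat 3 (33.8, 9.71 and 1009 CPM) lay far above those of the other membranes. The other 19 lists did not pass camera, among them the endothelial list, at a median of 0.08 over 15 genes (adjusted p = 0.499), and the proliferation list, at 0.00 over 21 genes (adjusted p = 0.601). Median, mean or test differed in sign for the osteoblast, BMP and TGF-beta ligand, Wnt ligand, Wnt antagonist and proliferation lists.

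In total 111 of 12857 genes differed between membrane and PFNU, 47 higher and 64 lower, and 91 of them by at least 2-fold (29 higher, 62 lower). With RLE size factors 27 were higher and 62 lower. The number depended strongly on the method: DESeq2 called 572 genes, limma-voom with quality weights 0 (1558 with an unadjusted p under 0.05) and edgeR on the 8 libraries alone 0 (1323 unadjusted, against 1997 in the fit of all 16). A replicate block for rat gave 47 genes (10 higher, 37 lower), and 9 named genes (Fbn1, Loxl1, S100a9, Mmp8, Gfpt2, Chpf, Tgfbi, Myl3 and Myh2) then had adjusted p of 0.0507 to 0.0849. With that block 1 neutrophil gene was called in place of 7, neither fibrous matrix gene was (Fbn1 0.0507, Loxl1 0.0648), and Nbl1 had adjusted p = 0.0736. Leaving out membranes 1 to 4 gave 49, 38, 196 and 244 genes, and leaving out PFNU libraries 1 to 4 gave 107, 31, 32 and 11. Of 20 called named genes 4, among them Cd79b, Rag1 and Myh7, were called whichever library was left out. No neutrophil gene was called without PFNU of rat 2, 3 or 4, and 1, 4, 4 and 3 were without membranes 1 to 4. B cell genes numbered 4 without membrane 1 and 3 without PFNU of rat 4. With the erythroid covariate 2 genes were called in all, neither of them a B cell or neutrophil gene. Those lists then had medians of -1.85 and -1.55 (camera adjusted p = 2.15e-11 and 1.22e-06 at the preset correlation). Even without the covariate, camera with an estimated correlation gave them adjusted p of only 0.0889 and 0.157.

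**Figure D3:**
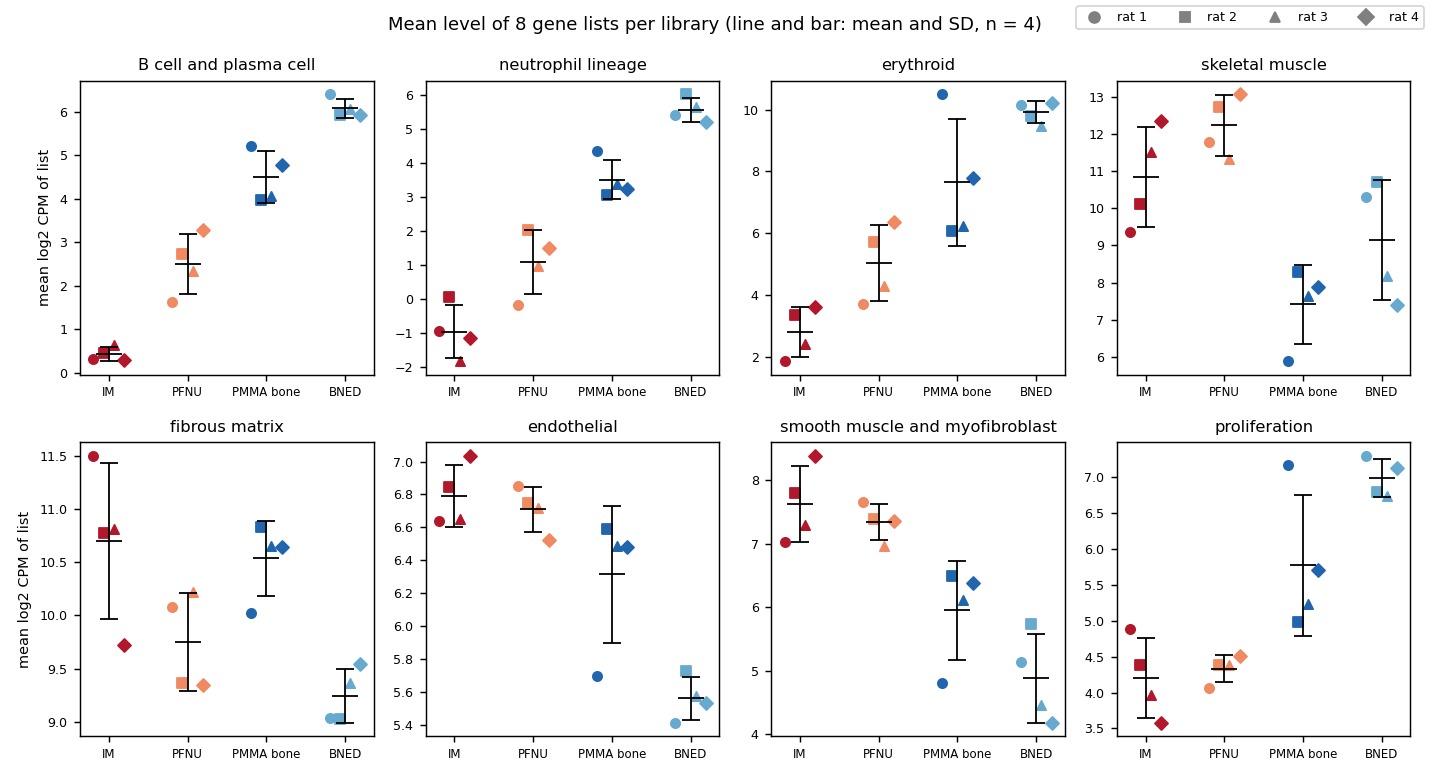
Points are the mean log2 CPM of each of 8 gene lists in each library by group, with a symbol per rat, and lines and bars are the mean and SD of 4 rats. B cell, neutrophil and erythroid levels are lowest in IM and highest in BNED, with the PMMA bone of rat 1 near BNED for erythroid genes.

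Bone beside the spacer was compared with bone beside the empty defect to see whether the spacer affects the neighbouring bone. Some matrix, vessel and smooth muscle genes, a minority of each list over all genes tested, were higher beside the spacer. Thbs2, a matricellular protein of connective tissue, was at 1080 ± 416 CPM (SD, n = 4) beside the spacer and 189 ± 37.4 CPM beside the empty defect (log2 fold change 2.52, SE 0.54, adjusted p = 0.0257). Of 18 fibrous matrix genes 6 rose (16 adjusted over the list alone, median 1.28, camera adjusted p = 4.47e-11, and adjusted p = 0.172 with an estimated correlation). Among them were Loxl2, a collagen crosslinking enzyme (1.62, SE 0.33, adjusted p = 0.0228), and Col6a2 (1.61, SE 0.37, adjusted p = 0.0313). Of 15 endothelial genes 6 rose (12 adjusted over the list alone, median 0.77, camera adjusted p = 1.79e-08, and adjusted p = 0.172 with an estimated correlation). Flt1, a VEGF receptor, rose by 0.99 (SE 0.19, adjusted p = 0.0195), Plvap of fenestrated vessels by 1.39 (SE 0.27, adjusted p = 0.0210) and the endothelial transcription factor Erg by 0.82 (SE 0.18, adjusted p = 0.0250). Of 10 smooth muscle and myofibroblast genes 4 rose (8 adjusted over the list alone, median 1.28, camera adjusted p = 2.10e-05, and adjusted p = 0.229 with an estimated correlation). Acta2 was at 193 ± 82.4 against 58.9 ± 21.1 CPM (1.71, SE 0.36, adjusted p = 0.0250), and Actg2 (1.98, adjusted p = 0.0263) and Tagln (1.78, adjusted p = 0.0313) rose with it. Directional fry gave adjusted p of 0.00869, 0.00761 and 0.0204 for the fibrous matrix, endothelial and smooth muscle lists. Beside these groups of genes the erythroid share was 0.436 to 1.33% in 3 of 4 PMMA bone libraries and 4.15 to 7.23% in BNED.

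Some genes of the growth factor and antagonist lists, a minority of each over all genes tested, were also higher beside the spacer. Directional fry adjusted p was 0.00761 each for BMP and TGF-beta ligands and antagonists, 0.0204 for Wnt ligands and 0.00869 for Wnt antagonists. It was 0.0130 for angiogenic factors, 0.0204 for matrix proteases and 0.0787 for inflammatory cytokines. Of 14 BMP and TGF-beta ligands 3 rose (5 adjusted over the list alone, camera adjusted p = 2.48e-04, and adjusted p = 0.172 with an estimated correlation). They were Tgfb3 (86.5 ± 30.2 against 30.2 ± 7.27 CPM, SD, n = 4, log2 fold change 1.52, SE 0.27, adjusted p = 0.0174), Tgfb2 (1.00, adjusted p = 0.0262) and the activin subunit Inhba (2.43, adjusted p = 0.0400). Of 14 antagonists 3 rose, among them Nbl1 (1.44, adjusted p = 0.0230) and Chrd (1.43, adjusted p = 0.0397). In that list 5 rose when adjusted over the list alone (camera adjusted p = 8.54e-04, and adjusted p = 0.172 with an estimated correlation). Of 20 Wnt ligands and targets Wnt5b (1.55, adjusted p = 0.0371) and Wnt5a (1.10, adjusted p = 0.0428) rose (5 adjusted over the list alone, camera adjusted p = 0.00132, and adjusted p = 0.244 with an estimated correlation). Of 9 Wnt antagonists Dkk3 (1.67, adjusted p = 0.0283) and Sfrp2 (1.65, adjusted p = 0.0345) rose, both also adjusted over the list alone (camera adjusted p = 0.00855, and adjusted p = 0.172 with an estimated correlation). Of 14 angiogenic factor genes Pdgfa (1.23, adjusted p = 0.0174) and Pgf (0.90, adjusted p = 0.0357, and 0.0509 with a replicate block for rat), chosen after their values were seen, rose. Adjusted over the list alone 3 rose and 1 fell, and the list did not pass camera (adjusted p = 0.136). Of 18 matrix proteases and inhibitors 4 rose, including Mmp14 (1.65, adjusted p = 0.0338), Timp2 (1.48, adjusted p = 0.0254) and Adamts1 (1.25, adjusted p = 0.0327). Adjusted over the list alone 10 rose and 1 fell (camera adjusted p = 1.31e-05, and adjusted p = 0.244 with an estimated correlation). Of 21 inflammatory cytokines 3 rose (5 adjusted over the list alone, camera adjusted p = 2.32e-04, and adjusted p = 0.298 with an estimated correlation). They were the chemokines Cxcl2 (8.43 ± 9.37 against 0.173 ± 0.163 CPM, log2 fold change 5.64, SE 1.15, adjusted p = 0.0230) and Cxcl3 (1.14 ± 1.24 against 0.0277 ± 0.0343 CPM, adjusted p = 0.0285), and Il6 (2.92 ± 2.99 against 0.213 ± 0.0873 CPM, log2 fold change 3.75, SE 0.94, adjusted p = 0.0364). Cxcl3 had 0 to 6 counts in the BNED libraries. Fmod (2.30, adjusted p = 0.0394) and Col14a1 (1.87, adjusted p = 0.0371) of tendon and ligament, the hypoxia gene Car9 (1.98, adjusted p = 0.0341) and Junb (0.98, adjusted p = 0.0397) also rose.

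Among called genes of at least 5 CPM with no overlap between the groups, the largest increases were of Arg1 of arginine metabolism (log2 fold change 3.01, SE 0.70, adjusted p = 0.0315), Megf6 (2.74, adjusted p = 0.0216), Fndc1 (2.60, adjusted p = 0.0338) and Thbs2. Next came Itgb4, which anchors epithelial and Schwann cells to laminin (63.1 ± 32.5 against 11.2 ± 5.97 CPM, SD, n = 4, 2.49, SE 0.47, adjusted p = 0.0189), and Cpxm2 (2.46, adjusted p = 0.0250). B cell and neutrophil genes were in part lower beside the spacer. Their lists had directional fry adjusted p of 0.00631 and 0.00761, against 0.0744, 0.106 and 0.106 for the erythroid, osteoblast and osteoclast lists. Of 12 B cell and plasma cell genes 6 fell (11 adjusted over the list alone, median -1.53, camera adjusted p = 4.47e-11, and adjusted p = 0.172 with an estimated correlation). They included Cd79b (69.6 ± 20.9 against 241 ± 42.2 CPM, -1.79, SE 0.38, adjusted p = 0.0250), Fcrla (-1.90, adjusted p = 0.0174) and Cd22 (adjusted p = 0.0230). Of 16 neutrophil lineage genes 5 fell (13 adjusted over the list alone, median -2.12, camera adjusted p = 3.17e-10, and adjusted p = 0.172 with an estimated correlation). They included Ngp (-2.83, adjusted p = 0.0313), the antimicrobial peptide gene Camp (-2.65, adjusted p = 0.0397), Np4 (-2.46, adjusted p = 0.0469) and S100a9 (142 ± 83.1 against 628 ± 55.5 CPM, -2.14, SE 0.56, adjusted p = 0.0401). The platelet gene Gp5 (-2.79, adjusted p = 0.0338), the T cell gene Cd3g (-1.58, adjusted p = 0.0350) and the fast-muscle genes Myh4 (-3.73, adjusted p = 0.0345) and Pvalb (-3.29, adjusted p = 0.0468) fell. The muscle share was 0.199 to 1.24% beside the spacer and 0.438 to 4.72% beside the empty defect. Erythroid genes had a median of -1.12 over 11 genes (camera adjusted p = 7.54e-05, and adjusted p = 0.298 with an estimated correlation) and proliferation genes -0.93 over 21 (2.37e-10, and adjusted p = 0.244 with an estimated correlation). No gene of either list was called by edgeR over all genes or over the list alone. Unadjusted p was under 0.05 for 0 and 12, DESeq2 called 0 and 4, and limma-voom 11 and 21. Osteoblast genes had a median of 0.95 over 13 (adjusted p = 0.00344, and 0.356 with an estimated correlation) and osteoclast genes 1.02 over 13 (adjusted p = 0.00329, and 0.356 with an estimated correlation). Again no gene of either was called by edgeR over all genes, (1 and 0 rose when adjusted over each list alone), with 3 and 5 genes at an unadjusted p under 0.05, DESeq2 calling 2 and 3 and limma-voom 7 in the former and 9 higher and 1 lower in the latter. Of the panel Il6 alone was called. Acp5 (1.43, adjusted p = 0.153), Col1a1 (1.14, adjusted p = 0.226), Sp7 (1.06, adjusted p = 0.481), Bglap (0.45, adjusted p = 0.771) and Bmp2 (0.17, adjusted p = 0.816) were not, nor were Sost (0.54, adjusted p = 0.774), Vegfa (0.55, adjusted p = 0.468), Il1b (0.63, adjusted p = 0.500) and Prg4 (0.47, adjusted p = 0.580). Camera at the preset correlation was also passed upward by the cartilage, tendon, hypoxia, immediate early and osteocyte lists (adjusted p = 0.00164, 3.73e-04, 0.00412, 0.00433 and 0.0434, and adjusted p = 0.298, 0.191, 0.172, 0.248 and 0.389 with an estimated correlation). It was passed downward by the T cell, skeletal muscle and adipocyte lists (2.53e-04, 7.11e-06 and 2.32e-04, and adjusted p = 0.298, 0.298 and 0.248 with an estimated correlation). The osteocyte list did not pass without the PMMA bone of rats 1 or 4 or BNED of rats 1 or 2 (adjusted p = 0.147, 0.0518, 0.0586 and 0.174). For the macrophage list the median was -0.02 and the mean 0.11, and the synovial lining list had a median of 0.33 with a downward test (adjusted p = 0.846).

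In all 631 genes differed between PMMA bone and BNED, 451 higher and 180 lower, and 416 of them by at least 2-fold (298 higher, 118 lower). DESeq2 called 1546 genes, limma-voom 6244 and edgeR on the 8 libraries alone 1767. A replicate block for rat gave 454 (308 higher, 146 lower), and 11 named genes (among them Arg1, Sfrp2, Myh4, Cd3g, Fmod, Junb, Inhba, S100a9, Pvalb and Np4) then had adjusted p of 0.0509 to 0.0723. With that block 3 fibrous matrix, 3 endothelial, 1 Wnt antagonist and 1 tendon gene rose and 2 neutrophil genes fell, and 2 osteoblast genes were called higher. The count rested on single libraries: it was 2578 without the PMMA bone of rat 1, in which all 631 were again called. It was 0 without the PMMA bone of rat 2, 3 or 4 (2050, 2019 and 2318 at an unadjusted p under 0.05, against 3130 in the full fit). It was 0 without BNED of rat 1 or 3 (2187 and 2654), 271 without BNED of rat 2 and 350 without that of rat 4. None of the 45 called named genes was called whichever library was left out. Without BNED of rat 2 or rat 4, 2 and 3 fibrous matrix, 4 and 3 endothelial, 3 and 2 smooth muscle and 1 and 1 protease genes rose, and 4 and 4 B cell and 0 and 1 neutrophil genes fell by edgeR. Without the PMMA bone of rat 1, 10 fibrous matrix, 11 endothelial and 8 smooth muscle genes rose, and 9 B cell, 12 neutrophil, all 11 erythroid and all 21 proliferation genes fell. With an erythroid covariate edgeR called 0 genes (1006 at an unadjusted p under 0.05), and the medians were 0.67 for fibrous matrix, 0.50 for endothelial, 0.84 for smooth muscle, -0.94 for B cell and -1.25 for neutrophil genes. The cytokine list then did not pass (adjusted p = 0.0892). With a muscle covariate the cytokine, osteoclast, osteocyte, Wnt antagonist and immediate early lists did not pass (adjusted p = 0.117, 0.0677, 0.350, 0.0797 and 0.1097).

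**Figure D4:**
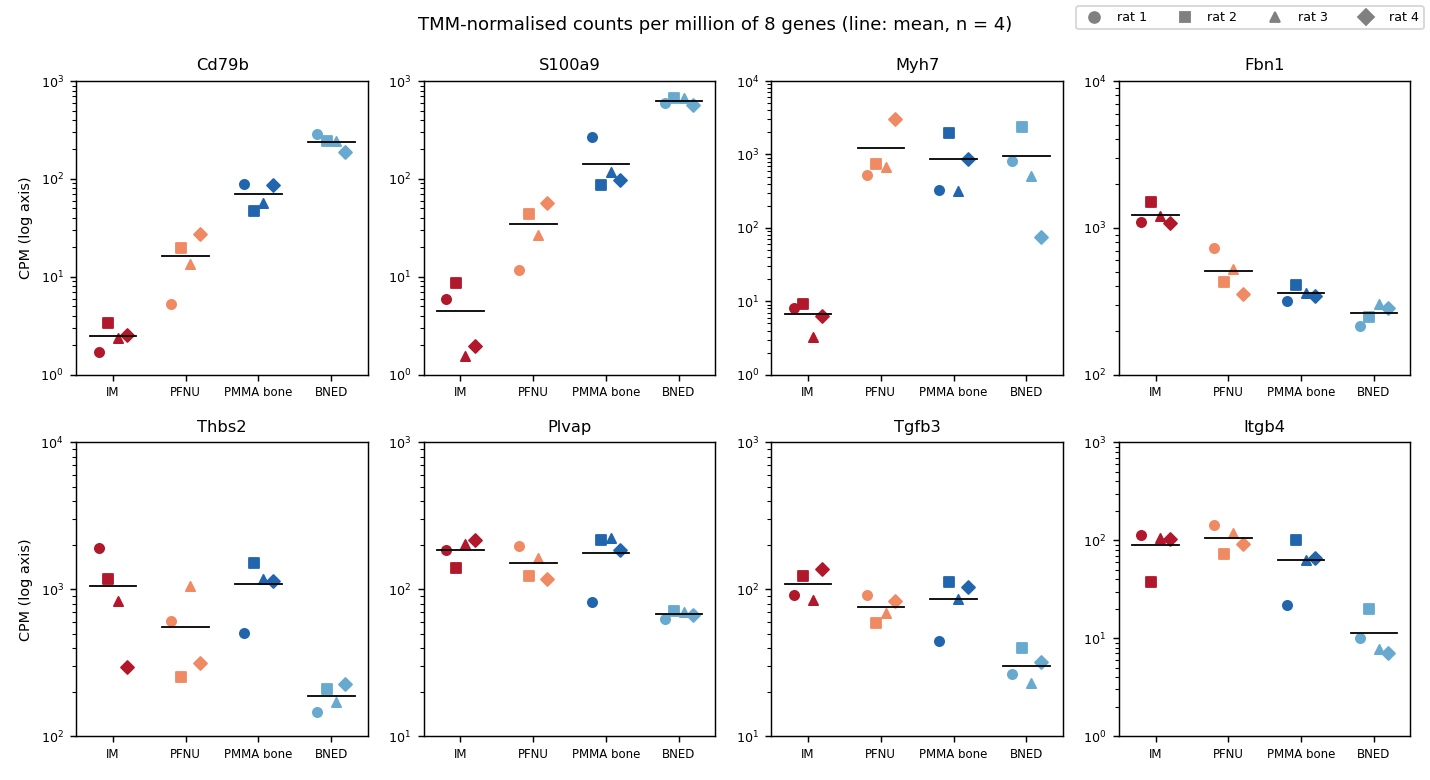
CPM on a log axis is plotted for 8 genes in each library by group, with a symbol per rat and a line at the mean of 4 rats. Cd79b and S100a9 are lower and Fbn1 is higher in IM than in PFNU, and Thbs2, Plvap, Tgfb3 and Itgb4 are higher in PMMA bone than in BNED.

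Whether the effect of the spacer differed between defect tissue and bone was tested as the difference of the 2 log2 fold changes. No gene passed with edgeR: the lowest adjusted p was 0.0674 and 1149 genes had an unadjusted p under 0.05. DESeq2 called 136 genes and limma-voom 218. The count was 199 without the PMMA bone of rat 1 and 2 without PFNU of rat 1, and 0 without any other library. The panel genes had differences from -3.58 (SE 1.23, adjusted p = 0.420) for Il6 to 0.14 (SE 0.69, adjusted p = 0.974) for Prg4. Of the lists, 16 passed camera at the preset correlation, with no call by edgeR in any of them. Endothelial genes had a median difference of -0.59 (camera adjusted p = 1.64e-06, and adjusted p = 0.277 with an estimated correlation) and proliferation genes 0.92 (5.49e-09, and adjusted p = 0.339 with an estimated correlation). At an unadjusted p under 0.05 there were 7 and 0 genes, DESeq2 called 1 and 0 and limma-voom 3 and 0, and without the PMMA bone of rat 1 edgeR called 4 lower endothelial and 7 higher proliferation genes. With a replicate block for rat, the osteocyte (adjusted p = 0.0418) and adipocyte (adjusted p = 0.0446) lists also passed and the nerve list did not (adjusted p = 0.0640).

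Calls made in both the defect tissue and the bone comparison, which share no libraries but come from the same 4 rats and limbs, were counted against independent lists. The p-values assume independence and do not allow for the shared animals. Among genes higher with the spacer 15 were shared against 1.65 expected (Fisher's exact p = 3.19e-11), and among lower genes 21 against 0.896 (p = 8.72e-24). The lower genes included Cd79b, Ms4a1, S100a8, S100a9 and Ngp. Genes are not independent replicates, and the log2 fold changes of all genes correlated at r = 0.41 across genes.

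Defect tissue differed from neighbouring bone in each limb. The membrane had 2860 genes different from PMMA bone, 1447 higher and 1413 lower (1961 by at least 2-fold). By the same limits of level and overlap, the largest increases were of the fast-muscle genes Myh4 (log2 fold change 8.70, SE 1.14, adjusted p = 3.33e-04), Fbp2 (8.44, SE 1.11) and Pvalb (7.63, SE 1.09). The largest decreases were of the lymphocyte genes Rag1 (-7.72, SE 0.79, adjusted p = 4.88e-05) and Igll1 (-7.27, SE 0.72) and of Camkv (-7.44, SE 0.92, 0 to 5 counts per membrane). In the skeletal muscle list 13 of 17 genes rose and 2 fell, also when adjusted over the list alone (adjusted p = 0.306 with an estimated correlation). Of marrow genes 11 of 12 B cell, 13 of 16 neutrophil and 11 of 11 erythroid genes fell (11, 14 and 11 adjusted over each list alone; adjusted p = 0.0581, 0.0581 and 0.273 with an estimated correlation). Of 13 osteoblast genes 8 fell (10 adjusted over the list alone, median -2.63, camera adjusted p = 4.16e-07, and adjusted p = 0.273 with an estimated correlation), and of 13 osteoclast genes 9 fell (12 adjusted over the list alone, median -2.18, camera adjusted p = 5.93e-09, and adjusted p = 0.273 with an estimated correlation). Osteoblast genes called numbered 4 without the membrane of rat 2 or 4 and 5 without the PMMA bone of rat 4. The count of all genes was 1818 without the membrane of rat 4, 1842, 1903 and 1891 without the PMMA bone of rats 1, 3 and 4, and 908 with the 8 libraries alone.

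PFNU had 3884 genes different from BNED, 1928 higher and 1956 lower (2504 by at least 2-fold). By the same limits, the largest increases were of Ubd (log2 fold change 5.41, SE 1.21, adjusted p = 0.00424), Cxcl11 (5.02, SE 1.20, adjusted p = 0.00665) and Ccl11 (4.70, SE 0.55, adjusted p = 1.20e-04). The first pair are interferon-induced, and Ccl11 is a chemokine of eosinophils. Ubd and Cxcl11 were far higher in PFNU of rat 1 (91.9 and 81.0 CPM) than in the others. The largest decreases were of granulocyte genes, Prg3 (-6.95, SE 0.95), Prtn3 (-6.58, SE 0.94) and Ctsg (-6.27, SE 0.90). These had 0 to 24, 0 to 15 and 2 to 81 counts per PFNU library, the highest in rat 2, so the size and rank of the changes are uncertain. All 12 B cell, 15 of 16 neutrophil, all 11 erythroid and all 21 proliferation genes fell (12, 15, 11 and 21 adjusted over each list alone; adjusted p = 0.0497, 0.0863, 0.313 and 0.183 with an estimated correlation). Higher in PFNU were 14 of 15 endothelial, 12 of 17 skeletal muscle and 8 of 10 smooth muscle genes (15, 13 and 10 adjusted over each list alone; adjusted p = 0.183, 0.460 and 0.183 with an estimated correlation). Muscle genes called numbered 6 without BNED of rat 3. limma-voom called 6720 genes. By edgeR 1447 were called with the muscle covariate and 0 with the erythroid covariate (3027 at an unadjusted p under 0.05). With a replicate block for rat, the osteocyte (adjusted p = 0.0329) and cartilage (adjusted p = 0.0361) lists also passed camera. Across genes the fold changes of the 2 tissue comparisons correlated at r = 0.80, and 915 higher and 976 lower genes were shared, where independent lists would share 217 and 215. These comparisons too come from the same 4 rats.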

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

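Of the tests weighed here, only the position of the PMMA bone library of rat 1 between the bone groups was chosen before its result was seen, and the other tests of an explanation were chosen after.

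Of B cell genes 7 of 12 and of neutrophil genes 7 of 16 were called lower in the membrane than in PFNU. With an estimated correlation the lists had camera adjusted p of 0.0889 and 0.157, and their directional fry adjusted p were 0.0128 and 0.0348. With a replicate block for rat, Ngp alone of the 7 neutrophil genes stayed called. No neutrophil gene was called without PFNU of rat 2, 3 or 4. An effect of the spacer on the cells of the tissue stays open and untested. The macrophage list did not fall, with a median of 0.80 (camera adjusted p = 7.02e-06, and adjusted p = 0.485 with an estimated correlation). None of its genes was called by edgeR, and with the muscle covariate its camera adjusted p was 0.184. A smaller share of marrow in the membrane may account for the lower genes, since marrow brings B cell precursors, granulocyte precursors and erythroid cells together: the medians of the B cell, neutrophil and erythroid lists were -2.66, -2.46 and -2.22 and spanned only 0.439. Whether the muscle content of the libraries accounts for the lower genes cannot be decided. With a muscle covariate 14 of 14 called B cell and neutrophil genes were still lower past the threshold. The covariate has a single slope for all groups, however. In PFNU the muscle and B cell levels were both highest in rat 4 (13.1 and 3.29 log2 CPM). In PMMA bone, rat 1 had the lowest muscle level (5.87) and the highest B cell level (5.22). Of 35 splits of the 8 libraries 3 gave at least the real 111 genes, so chance was not excluded (the other 7 that part all rat pairs gave 0 by edgeR). The highest other, with 1835 genes, set membranes 1 and 2 and PFNU 1 and 3, which had the lower muscle shares within their groups, against the rest. The next, with 922 genes, set rats 1 and 3 against rats 2 and 4 in both tissues. It did not follow the muscle share of the membranes (18.3% in rat 3 and 4.55% in rat 2). Both splits point to a structure of the samples.

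Of matrix, vessel and smooth muscle genes, 6 of 18, 6 of 15 and 4 of 10 were called higher in bone beside the spacer. With an estimated correlation their lists had camera adjusted p of 0.172, 0.172 and 0.229, and their directional fry adjusted p were 0.00869, 0.00761 and 0.0204. No gene was called without the PMMA bone of rat 2, 3 or 4 or BNED of rat 1 or 3. A response of bone to the spacer stays open as a hypothesis. Whether a lower marrow share raised every other cell type alike cannot be decided with the lists used. The fibrous matrix level rose over the skeletal muscle level by 3.02 and over the macrophage level by 1.13 (log2, above 0 in 4 of 4 rats). The SD of these differences within rats was 2.198 and 0.567. A two-sided exact permutation test gave p = 0.0286 each when it ignored the rats and p = 0.125 with exchanges within rats. Each is the smallest its design can give. Marrow may itself hold macrophages, and the muscle share varied within a group (0.438 to 4.72% of counts in BNED), so neither list is a fixed reference. Marrow share as the only difference cannot be told apart from an effect of the spacer, because marrow share and group go together in 3 of 4 rats (in rat 1 it was 7.83% beside the spacer, above all BNED libraries) and 1 library decides nothing: with an erythroid covariate the median of the 16 called genes went from 1.46 (median SE 0.367) to 0.789 (median SE 0.314), all 16 stayed positive and 0 stayed called, as the smaller fold no longer passed. Of 35 splits 2 gave at least the real 631 genes, so chance was not excluded, and the other splits that part all rat pairs gave 0 by edgeR. The highest other split, with 1084 genes, set the PMMA bone of rat 1 with BNED 1, 3 and 4, which points to a structure of the samples.

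The PMMA bone of rat 1 resembled BNED. Whether it was swapped with a BNED library cannot be decided. The lowest erythroid share in BNED was 4.15% and the highest in the other 3 PMMA bone libraries 1.33%. That would go against a swap only if bone beside the spacer always had a low share. In rat 1 the shares were 7.83% in PMMA bone and 7.16% in BNED, so a swap within that rat would not show in them. A single wrong label cannot be told apart from a real likeness: over 2574 genes called without it, on a scale from 0 (BNED) to 1 (the other PMMA bone libraries), its median position was 0.195, and BNED libraries placed the same way lay at -0.147, 0.238, 0.123 and 0.0282. More marrow in this library stays open: its matrix and osteoblast genes lay at 0.520 (11 genes) and its marrow genes at 0.329 (32 genes, above the 0.195 of all genes). On those 11 genes BNED libraries, looked at afterwards, lay at -0.204 to 0.145. The BNED libraries had taken part in the choice of these genes and the PMMA bone of rat 1 had not, so these placements are not alike. The difference between its matrix and osteoblast genes and its marrow genes was 0.191, with a spread of 0.112. That is under the 0.3 asked of this explanation, though by less than the spread, and allowing for the spread was decided after the value was seen. The marrow lists did not lie alike in this library. Its erythroid level (10.5 log2 CPM) was above all BNED libraries (9.46 to 10.2). Its B cell (5.22) and neutrophil (4.35) levels lay between BNED (5.93 to 6.40 and 5.21 to 6.03) and the other PMMA bone libraries (3.97 to 4.78 and 3.07 to 3.39).

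Splits of the libraries of the other comparisons gave these counts. For the membrane against PMMA bone 1 of 35 splits, the real one with 2860 genes, reached that number, and the highest other split gave 73. For PFNU against BNED 1 of 35 did, with 3884 genes against 0 by edgeR. In both comparisons the real split alone reached its count over all 35 splits, which ignore the shared rats. The 8 that part all rat pairs are too few for a share under 0.05, so with the pairing kept chance cannot be excluded. For the difference of the spacer effects all 100 drawn splits reached the real count of 0 by edgeR (1149 at an unadjusted p under 0.05, 136 by DESeq2 and 218 by limma-voom), and since no split can give fewer than 0 this says nothing about chance. The highest gave 1124.

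Single samples stood far from the other 3 of their group in 27 of 325 groups of 4 tested. Chance gives about 1 in 20 for independent, normally distributed values. The values here included CPM and shares and came from genes that move together, so an excess over chance is not shown. In the PMMA bone of rat 1 the erythroid share was 7.83% (others 0.436 to 1.33%), the endothelial list level 5.70 log2 CPM (6.48 to 6.59), the interferon list level 4.96 (3.67 to 3.84), Megf6 18.1 CPM (58.2 to 63.4), Np4 68.9 CPM (15.5 to 22.6) and Tagln 96.1 CPM (293 to 326). In PFNU of rat 4 the muscle genes Myh7, Myl2, Tnnc1 and Tnnt1 were at 3031, 519, 551 and 1178 CPM (others at most 734, 163, 155 and 295). In PFNU of rat 1 Cxcl11 was at 81.0, Ubd at 91.9 and Gfpt2 at 46.1 CPM (others at most 8.71, 10.5 and 24.8), and in PFNU of rat 2 the adipocyte list was at 6.22 log2 CPM (4.12 to 4.36) and Prg3 at 0.467 CPM (0 to 0.0623). In the membrane of rat 3 Acp5 was at 1009, Sost at 9.71 and Sp7 at 33.8 CPM (others at most 225, 0.452 and 3.00) and the angiogenic factor list at 4.53 log2 CPM (4.26 to 4.30), and in the membrane of rat 2 Gap43 was at 52.9 and Sbsn at 34.0 CPM (others 12.36 to 16.04 and 9.54 to 12.6). In BNED of rat 4 Car9, Cxcl2 and Fmod were at 6.08, 0.415 and 382 CPM (others at most 2.00, 0.121 and 124), in BNED of rat 2 Acta2 and Chrd at 90.2 and 14.9 CPM (51.7 and 6.51), and in BNED of rat 3 Sp7 at 45.2 CPM (22.1 to 25.9).

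The spacer effect differed between defect tissue and bone for 16 lists by camera at the preset correlation, and for none with an estimated correlation. Median differences were below 0, meaning a smaller or more negative effect in defect tissue, for the osteoblast list (-0.62, adjusted p = 0.00178), osteoclast (-0.96, 7.80e-05), BMP and TGF-beta ligand (-0.73, 1.92e-04), BMP and TGF-beta antagonist (-0.62, 0.0115), Wnt ligand (-0.74, 4.01e-04), Wnt antagonist (-0.68, 0.0464), endothelial (-0.59, 1.64e-06), angiogenic factor (-0.43, 0.0245), cytokine (-0.64, 0.00888), smooth muscle (-0.64, 0.0115), tendon (-1.13, 0.0115), nerve (-0.52, 0.0419) and hypoxia (-0.62, 0.0196) lists. They were above 0 for the macrophage (0.68, 4.01e-04), T cell (0.59, 0.0245) and proliferation (0.92, 5.49e-09) lists. With an estimated correlation the adjusted p of the 16 lists ran from 0.277 to 0.692. The call also ended with the muscle covariate for the Wnt antagonist (adjusted p = 0.0532), angiogenic factor (0.0708) and nerve (0.0614) lists, and with the erythroid covariate for nerve (0.0690). Leaving out 1 library ended the call at the preset correlation for 8 of them. The adjusted p then reached 0.266 for the T cell list (6 libraries), 0.162 for Wnt antagonists (8), 0.151 for cytokines (3), 0.1305 for nerve (8), 0.0947 for angiogenic factors (5) and tendon (2), 0.0768 for smooth muscle (3) and 0.0525 for BMP and TGF-beta antagonists (1).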

How the results depend on the processing

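The skeletal muscle and erythroid covariates were the only tests here chosen after the data were seen. Counts of differing genes moved most. For membrane against PFNU (111) they were 572 with DESeq2, 0 with limma-voom, 0 with the 8 libraries alone, 47 with a replicate block, 427 with the muscle covariate, 2 with the erythroid covariate (Ell3 and Glrx5, chosen after their values were seen, adjusted p = 0.0327) and 11 to 244 with a library left out. For PMMA bone against BNED (631) they were 1546, 6244 and 1767 with DESeq2, limma-voom and the 8 libraries, 2123 with the muscle and 0 with the erythroid covariate (1006 unadjusted), and 0 to 2578 with a library left out. For the difference of the effects (0) they were 136, 218, 31 and 5 with DESeq2, limma-voom, the muscle and the erythroid covariate, and 0 to 199 with a library left out. For the membrane against PMMA bone (2860) they were 834 and 974 with the covariates, 908 with the 8 libraries and 1818 to 4047 with a library left out, and for PFNU against BNED (3884) 6720 with limma-voom, 1447 and 0 (3027 unadjusted) with the covariates and 2637 to 3981 with a library left out. Size factors and filters on low counts kept all 5 counts within 1.5 times. The cause of these shifts was not tested.

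No named gene turned direction. The adjusted p of lists in this paragraph are from camera at the preset correlation. For membrane against PFNU all 20 called named genes lost their call with limma-voom, with the 8 libraries and with the erythroid covariate. With that covariate all 45 for PMMA bone against BNED and all 6 for PFNU against BNED also did, and with DESeq2 none did. The muscle covariate ended the calls of Tgfbi, Tnnc1, Myl3 and Myh2 (adjusted p = 0.0599, 0.0706, 0.0919 and 0.147) in membrane against PFNU, Il6 and Junb (0.0558 and 0.0636) in PMMA bone against BNED, and Ubd (0.0678) in PFNU against BNED. In PMMA bone against BNED limma-voom ended that of Cxcl2 (0.0891) and called Acp5, Col1a1, Sp7 and Vegfa (0.00771, 0.00695, 0.0384 and 0.0181), and the 8 libraries ended that of Chrd (0.0556) and called Acp5, Col1a1 and Sp7 (0.0216, 0.0461 and 0.0482). Myh2 lost its call with RLE factors and with either other filter (adjusted p = 0.0564, 0.0512 and 0.0538), and Chrd in bone with the stricter filter (0.0507). The replicate block changed no call of a named gene or list beyond those given in the results, where its count for membrane against PFNU was 47. List directions turned with the erythroid covariate for adipocyte (adjusted p = 0.646) and proliferation genes (1.46e-05) in membrane against PFNU, for fibrous matrix (0.00514), protease (0.00123), endothelial (0.653) and proliferation genes (0.907) in membrane against PMMA bone, and for fibrous matrix and protease (0.0158 each) and cytokine genes (0.00213) in PFNU against BNED. They turned with the muscle covariate for macrophage genes in PMMA bone against BNED (0.0483) and T cell genes in membrane against PMMA bone (0.0360), and without PFNU of rat 1 for interferon genes in the difference of the effects (0.0354, the only library without which they passed; they turned without 6 of 16 libraries, with 0.0354 to 0.912 over all). The muscle and erythroid lists were not tested against the covariate made from them; those tests were dropped after their values, some of which had turned direction, had been seen. At 40472228 counts or more per library, depth limits few of the named genes, and low ones such as Cxcl3, with 0 to 6 counts in BNED, are limited most.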

Other observations

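The genes here were chosen after their values were seen, and of the alternatives the 2 covariates were added then. Alox5, the 5-lipoxygenase that starts leukotriene synthesis, was higher in the membrane than in PFNU (33.5 ± 6.94 against 16.7 ± 4.94 CPM, SD, n = 4, log2 fold change 1.00, SE 0.22, adjusted p = 0.0428) and lower in bone beside the spacer than beside the empty defect (19.96 ± 1.68 against 38.6 ± 8.35 CPM, -0.95, SE 0.22, adjusted p = 0.0294). Gas7 moved in the same way (1.08, SE 0.22, adjusted p = 0.0349 in defect tissue and -0.94, SE 0.22, adjusted p = 0.0321 in bone). These calls held in part of 25 alternatives: 9 for Alox5 (adjusted p up to 0.226) and 13 for Gas7 (up to 0.241) in defect tissue, and 18 for each in bone (up to 0.389). Of all genes called in both comparisons, these 2 had opposite signs. The test of the difference itself did not pass (Alox5 1.96, SE 0.31, and Gas7 2.02, SE 0.31, each adjusted p = 0.0674); it passed in 6 of 24 alternatives for each gene, with adjusted p from 2.28e-05 to 0.262 for Alox5 and from 2.45e-06 to 0.262 for Gas7, including 0.00774 for both without PFNU of rat 1, and with differences of 1.84 to 2.19 and 1.90 to 2.27. Between tissue and bone Alox5, its activating protein gene Alox5ap and the transferrin gene Tf were the 3 genes called with opposite signs: higher in the membrane than in PMMA bone (0.75, 1.04 and 0.93, adjusted p = 0.0235, 0.0174 and 0.0402) and lower in PFNU than in BNED (-1.21, -0.83 and -1.03, adjusted p = 0.00107, 0.0366 and 0.0205).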
